A study of Mus musculus with 4 samples.

How the data were processed

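The series measured polyadenylated RNA of single cells from the endothelial fraction of mouse hearts by Drop-seq. Per the labels' protocols, viable cells were selected by flow cytometry with the dye DAPI and packed in droplets with barcoded beads, and their cDNA was amplified by PCR before sequencing. The 4 samples were 2 sham and 2 TAC libraries, the latter taken 1 week after TAC, and groups and replicate numbers came from the sample titles. Columns of the count table were assigned to samples by the group and number in their names. Both TAC column names carry the same number after TAC, whose meaning is not given. The next number, which differs between them, was taken as the replicate. The table also held 1600 columns of 2 libraries that no sample label covers, and these were not used here.

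The count table that the authors deposited held raw whole-number counts for 15081 genes. The aligner, the counting program and whether counts were collapsed by molecular identifier are not given in the sources used here. The submitters' processing notes name the mm10 build and Seurat 4.0.2 without a role. A detected gene carried a mean of 8.17 to 24.3 counts per barcode, and 18.7% to 22.1% of detected entries held a single count, so the values look like reads of PCR products. The planned design took them for counts of molecules, and its count test was kept because it needs only whole-number counts. The second table the authors deposited listed cluster markers. Per the file headers it gives a p-value and an adjusted p-value of a Wilcoxon test over cells, the fraction of cells with the gene in the cluster and in the other cells, and a mean log fold. The deposited mean log fold is treated as a score, because its log base is not given in the sources used here. It was used for rank and sign, and for 1 stricter threshold, above 0.5 in the deposited scale with an adjusted p under 0.001. In all 673 entries the deposited adjusted p-value was the p-value times the number of genes in the count table, within 1%.

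Each library held 800 barcodes, and total counts ran from 1500132 to 2885607. Barcodes with at least 200 detected genes were kept, 1485 of 3200, and they held 49.1% and 73.5% of the counts in the sham libraries and 95.4% and 75.4% in the TAC libraries. Counts of each kept cell were scaled to 10000, log transformed and clustered with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.8), which gave 9 clusters. Clusters were named from marker lists. The rule for applying the lists was set after seeing the data: a cluster took the class with the highest mean log2 fold among classes with at least 3 markers found in at least 10% of its cells. It stayed unnamed where another class raised at least 3 markers 1.5-fold and at least 0.5 times as many as the first class, or had more markers among the top 10 genes. Doublets were called with Scrublet in scanpy within each library. It marked 24.3% and 9.03% of sham but 0.43% and 2.77% of TAC cells, so called cells were kept, and leaving them out was an alternative.

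Libraries were the replicates. Counts were summed per library over all kept cells and over endothelial-like cells. Genes were filtered with filterByExpr, scaled by TMM and compared with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05, for 8781 genes over all cells and 7907 in endothelial-like cells. Log2 fold changes are TAC over sham with the standard error of the fitted coefficient, and CPM are given as mean and SD over 2 libraries. A fold against a group without counts was set against a floor of 3 counts over the group, and with 1 to 3 counts a ratio is given with its 95% counting interval. If counts are reads, 1 molecule can give more than 3 of them, so such a fold is no lower bound and such an interval is too narrow. Gene lists with at least 5 measured genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, on log2 CPM with a prior count of 2, adjusted over the lists. Camera with an estimated correlation, and fry, which tests whether a list's genes move one way on balance, were alternatives. There were 22 lists of pathways and cell states and 18 of cell type markers. The tests of the lists over all cells and of the marker lists were added after seeing the data. Shares of cells were compared with a two-sided exact permutation test over the 4 libraries, where 2 against 2 cannot go below p = 0.333, and single shares have exact Clopper-Pearson 95% intervals. For the share of cells with a mesenchymal transcript each cell was thinned to 500 counts.

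The samples' groups, the tests, the gene and marker lists, the rule for named genes and the first set of other settings were fixed before the data were examined. Named were Col1a1, Col3a1, Col4a1, Fn1, Sparc, Vim, Tagln, Acta2, Cdh5 and Pecam1; the 8 largest rises and falls among genes that passed with the groups apart, or the 8 smallest p in each direction where none passed; and the 4 members with the smallest p of each list that passed. Positions of 66 of 67 such genes came from GENCODE M21 on GRCm38, the assembly also called mm10. The gene test was tested on simulated data with the means and sizes of the endothelial-like sums of 7907 genes. It called 4 of 100 genes with a 4-fold change, 28 of 100 with a 16-fold change and 0 of 7707 unchanged genes, while DESeq2 1.42.0 called 16, 49 and 41. The list test called the 1 shifted list and no other. Each simulated gene was drawn independently, so this does not test lists whose genes vary together between libraries.

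This first set of other settings was DESeq2's size factors, no filter, each library left out, the replicate number as a block, a stricter cell filter (500 counts and under 10% mitochondrial counts), called doublets left out, DESeq2's Wald test, resolutions of 0.4 and 1.2, 15 principal components, 1000 variable genes, thinning to 500 or 1000 counts or none, and at least 2 counts. Added after seeing the data were tests on the number of cells with each gene, the same on cells reduced to 200 detected genes drawn at random, tests without barcodes shared by the TAC libraries, a test on all deposited barcodes, shares among the 100 cells with the most detected genes, and camera with both the block and an estimated correlation. A fit with 1 library left out set 1 library against 2. Its spread came from the 2 libraries of the other group alone, and the lone library was assumed to vary like them. Counts and detected genes per cell differed between the groups, and no label gives a preparation or sequencing date, so a difference in library preparation between sham and TAC cannot be told apart from the operation.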

Results

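Single cells from the endothelial fraction of mouse hearts were profiled by Drop-seq, which captures the polyadenylated RNA of each cell on a barcoded bead inside an oil droplet. The mice were 8 to 9 weeks old and of mixed background, and had undergone either a sham operation or TAC, a surgical narrowing of the aorta with a 26-gauge constriction that puts a pressure load on the left ventricle. Hearts were taken 1 week after TAC, and each group held 2 libraries. The series asked whether pressure overload is accompanied by a partial endothelial to mesenchymal transition, in which endothelial cells gain transcripts of connective tissue cells such as collagens. Each library held 800 barcodes, with total counts of 2333331 and 1972493 in sham replicates 1 and 2 and of 2885607 and 1500132 in TAC replicates 1 and 2. The median number of detected genes per barcode was 87.0 and 150.5 in the sham libraries and 341.5 and 158.5 in the TAC libraries. Barcodes with at least 200 detected genes were kept as cells, which left 148 and 310 sham cells and 702 and 325 TAC cells. A detected gene carried a mean of 24.3 and 12.5 counts in the sham libraries and 8.41 and 8.17 in the TAC libraries, so the counts look like reads and not like single molecules. Intervals on shares of cells cover counting error of cells only. Intervals on ratios of counts treat every count as independent, which reads of the same molecule are not, so they are too narrow if counts are reads. Nothing in the labels says that libraries of 1 group came from separate animals, and the TAC libraries shared 8 barcode sequences where 0.038 were expected by chance. The p-values of the gene and share tests therefore measure only the spread between these libraries, which may be technical. Camera with its preset correlation compares genes inside a list with genes outside it. Its p-values do not take from the libraries how far the genes of a list vary together. Only camera with an estimated correlation and fry do so.

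Endothelial-like cells made up most of every library, and the TAC libraries held more fibroblast-like and macrophage-like cells than the sham libraries. Fibroblast-like cells, led by the matrix genes Mfap5, Col1a2, Col3a1 and Dcn, made up 0.65% ± 0.91 (SD, n = 2) of sham cells and 17.6% ± 1.35 (SD, n = 2) of TAC cells. Macrophage-like cells, led by the lysozyme gene Lyz2, the protease gene Ctss and the cytokine gene Il1b, made up 1.66% ± 0.52 (SD, n = 2) of sham cells and 8.05% ± 2.11 (SD, n = 2) of TAC cells. Endothelial-like cells made up 90.8% ± 0.63 (SD, n = 2) and 70.7% ± 2.12 (SD, n = 2), respectively. Schwann-like cells, led by the sodium channel gene Scn7a and the myelin gene Plp1, made up 3.30% ± 0.11 (SD, n = 2) of sham and 1.71% ± 0.20 (SD, n = 2) of TAC cells. A cluster led by the smooth muscle myosin Myh11, Cfh and the pericyte gene Rgs5 was left unnamed because it raised smooth muscle, pericyte and endocardial markers together. It made up 3.62% ± 0.35 (SD, n = 2) and 1.95% ± 1.15 (SD, n = 2).

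Per library, fibroblast-like cells numbered 0 of 148 in sham replicate 1, 4 of 310 in sham replicate 2, 130 of 702 in TAC replicate 1 and 54 of 325 in TAC replicate 2. The exact Clopper-Pearson 95% intervals ended at 2.46% and 3.27% in the sham libraries and began at 15.7% and 12.7% in the TAC libraries. For macrophage-like cells the sham intervals reached 5.81% and 3.27% and the TAC intervals began at 4.84% and 6.57%, so they overlapped between sham replicate 1 and TAC replicate 1. The two-sided exact permutation test gave p = 0.333 for each of the 5 classes, adjusted p = 0.333 over the classes, and 0.333 is the smallest value that 2 libraries against 2 can give. The shares depend on the minimum of 200 detected genes, which left out 652 and 490 sham barcodes and 98 and 475 TAC barcodes. Among the 100 cells with the most detected genes in each library, an alternative chosen after seeing the data, fibroblast-like cells were 41.0 percentage points more frequent in the TAC libraries, against 16.9 points over all kept cells. Among them macrophage-like cells were 3.5 points more frequent, against 6.39, at 2.0% and 2.0% in sham and 3.0% and 8.0% in TAC, and the endothelial-like difference was -37.5 points against -20.0. The difference was -2.5 points against -1.60 for Schwann-like cells, whose libraries then overlapped, and -4.5 against -1.67 for the unnamed cluster.

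**Figure D1:**
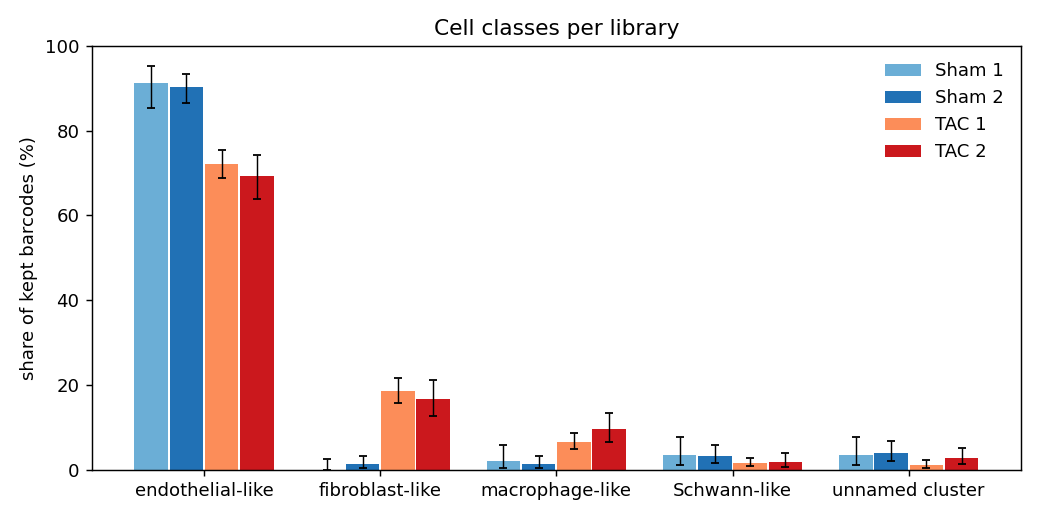
Share of kept barcodes, in percent, for the 4 named cell classes and the unnamed cluster in each of the 4 libraries. Bars are single libraries and error bars are exact 95% binomial intervals; the fibroblast-like share was 18.5% and 16.6% in the TAC libraries and 0.0% and 1.29% in the sham libraries.

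Summed over all kept cells of each library, 6 genes passed the test between TAC and sham. The fibrillar collagen gene Col1a2 rose by a log2 fold change of 4.81 ± 0.39 (SE), from 121 to 3388 CPM, the counts scaled to a common library total (adjusted p = 0.0418 in edgeR's quasi-likelihood test). Col3a1 rose by 4.29 ± 0.37 (SE), from 466 to 9121 CPM, with the same edgeR adjusted p. The growth factor gene Ptn rose by 4.37 ± 0.38 (SE; edgeR adjusted p = 0.0418), from 33.1 to 685 CPM. Col1a1 rose from 1 count in the sham libraries to 1168 in the TAC libraries, a ratio of normalised levels of 765 with a 95% counting interval of 137 to 30236 (edgeR adjusted p = 0.0476). The fatty acid transporter gene Cd36 fell by 1.79 on the log2 scale (SE 0.18), from 9020 to 2603 CPM. The pericyte gene Rgs5 fell by 2.61 (SE 0.26), from 1306 to 214 CPM, and both had edgeR adjusted p = 0.0476.

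All 6 genes stood apart between the groups, with both TAC libraries on one side of both sham libraries. Chance alone gives this for 33.3% of unselected genes. The 6 were picked by the test on the same libraries, so their separation adds no support. On the GRCm38 assembly, Col3a1 lies on chromosome 1 from 45311538 to 45349706 on the plus strand, Col1a2 on chromosome 6 from 4504814 to 4541544 on the plus strand, and Col1a1 on chromosome 11 from 94936224 to 94953042 on the plus strand. Ptn lies on chromosome 6 from 36714929 to 36810220 on the minus strand, Cd36 on chromosome 5 from 17781690 to 17888801 on the minus strand and Rgs5 on chromosome 1 from 169655501 to 169695813 on the plus strand. All are annotated as protein-coding. Of the genes named whatever their result, Sparc had a log2 fold change of 0.82 ± 0.19 (SE), Vim of 0.75 ± 0.22, Tagln of 5.40 ± 1.59 and Fn1 of 0.82 ± 0.97. Col4a1 had 0.15 ± 0.22, Acta2 -0.20 ± 0.36, Cdh5 -0.85 ± 0.39 and Pecam1 -0.85 ± 0.23. None of these 8 passed (edgeR adjusted p from 0.212 to 0.916).

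In the summed TAC cells, the matrix and collagen list and the mesenchymal transition list were higher in limma's camera test, and the capillary and endothelial identity lists were lower. With an estimated correlation none of the 4 passed (adjusted p = 0.340 to 0.360). The venous and lymphatic lists did not pass and pointed upward (camera adjusted p = 0.206 and 0.187). These tests over all cells were added after the design was fixed. They came with the 17.6% of fibroblast-like and 8.05% of macrophage-like cells in the TAC libraries, against 0.65% and 1.66% in sham. Of 40 measured matrix and collagen genes, 3 rose over all genes tested, 20 rose and 1 fell adjusted over the list alone, and the list was higher (camera adjusted p = 6.16e-06; adjusted p = 0.340 with an estimated correlation). Timp1, an inhibitor of matrix proteases, had 0 counts in sham and 1045 in TAC, and did not pass over all genes (edgeR adjusted p = 0.0541). It was 228-fold higher against a floor of 3 counts over the group, which is no lower bound if counts are reads. Of 31 mesenchymal transition genes, 3 rose over all genes and 6 adjusted over the list alone (camera adjusted p = 0.000987; adjusted p = 0.360 with an estimated correlation). Of 15 capillary genes, Cd36 fell over all genes and 11 fell adjusted over the list alone (camera adjusted p = 2.16e-06; adjusted p = 0.340 with an estimated correlation). Mgll, Rgcc and Kdr, the VEGF receptor gene, were among those with the smallest p, at log2 fold changes of -1.82 ± 0.22, -1.60 ± 0.26 and -2.00 ± 0.33 (SE). The endothelial identity list was lower, with 0 of 26 genes falling over all genes and 3 adjusted over the list alone, Ly6c1, Kdr and Esam (camera adjusted p = 4.80e-05; adjusted p = 0.340 with an estimated correlation).

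The cell cycle list was also higher in all TAC cells, with 34 of its 36 measured genes above 0, 0 rising over all genes and 1 adjusted over the list alone, the kinetochore gene Cenpf at 4.86 ± 0.60 (SE) (camera adjusted p = 1.27e-07; adjusted p = 0.340 with an estimated correlation). The inflammation and adhesion list was higher, with 9 of 22 genes rising adjusted over the list alone and 0 over all genes (camera adjusted p = 0.000469; adjusted p = 0.340 with an estimated correlation). Among the 9 were the cytokine gene Il6 at 5.93 ± 0.70 and the adhesion genes Icam1 at 3.21 ± 0.44 and Selp at 6.61 ± 1.24 (SE). The unfolded protein response list was higher, with 1 of 18 genes rising adjusted over the list alone, the chaperone gene Hspa5 at 1.35 ± 0.19 (SE), and 0 over all genes (camera adjusted p = 0.0331; adjusted p = 0.340 with an estimated correlation). The mitochondrially encoded list was lower, with 5 of 8 genes falling adjusted over the list alone and 0 over all genes, among them mt-Nd1 at -1.19 ± 0.26 (SE) (camera adjusted p = 0.00923; adjusted p = 0.340 with an estimated correlation). The endocardial, arterial and antigen presentation lists were lower in camera (adjusted p = 0.00763, 0.00923 and 0.0141), and had adjusted p = 0.340, 0.349 and 0.340 with an estimated correlation. Over all genes 0 of their members fell, and adjusted over the list alone 1 endocardial gene, 1 arterial gene and 0 antigen presentation genes fell. Their members with the smallest p were Cytl1 at -4.78 ± 1.12, Alpl at -4.52 ± 0.94 and H2-K1 at -0.82 ± 0.22 (SE), of which H2-K1 and H2-Q7 belong to a family of similar sequences and are uncertain. Fits without a library set 1 library against 2, took their spread from the pair alone and assumed that the lone library varied like it. Without Sham replicate 1 the camera calls of the endocardial (adjusted p = 0.0529), antigen presentation (0.0535) and mitochondrial lists (0.0753) ended. Without Sham replicate 2 those of the endocardial (camera adjusted p = 0.0848), arterial (0.161) and unfolded protein response lists (0.163) ended.

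Markers of other cells moved in the same sums. The fibroblast marker list was higher (camera adjusted p = 2.78e-08; adjusted p = 0.161 with an estimated correlation), with all 14 measured genes above 0 and 3 rising over all genes. The macrophage and monocyte list was higher (camera adjusted p = 6.45e-06; adjusted p = 0.238 with an estimated correlation), with 14 of 14 genes above 0 and 0 rising over all genes. The endothelial marker list (camera adjusted p = 4.84e-05) and the pericyte list (camera adjusted p = 8.48e-05) were lower, and both had adjusted p = 0.161 with an estimated correlation. Marker lists of Schwann, lymphatic endothelial, endocardial, smooth muscle and heart muscle cells did not pass (camera adjusted p = 0.0648, 0.107, 0.115, 0.502 and 0.766). Mitochondrial ribosomal RNA took 1.57% and 1.36% of the summed counts in the sham libraries and 0.94% and 0.97% in the TAC libraries. The count of 6 genes became 1472 without Sham replicate 1, 2659 without Sham replicate 2, 74 without TAC replicate 1 and 51 without TAC replicate 2, where the remaining pair alone gave the spread. DESeq2's Wald test called 445. The count became 652 and 171 on the number of cells with each gene, before and after each cell was reduced to 200 detected genes, both chosen after seeing the data, and 1 without called doublets.

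Within endothelial-like cells, the cell cycle list and the inflammation and adhesion list were higher in the TAC libraries and the capillary list was lower in camera, each with adjusted p = 0.602 with an estimated correlation. No single gene passed the test over all genes. Cenpf, which acts at the kinetochore in mitosis, stood at 14.1 ± 6.75 CPM in sham and 472 ± 16.5 in TAC (SD, n = 2). The heat shock gene Hsph1 stood at 61.0 ± 49.8 and 1303 ± 4.50, and the stress-responsive gene Ier3 at 161 ± 67.9 and 1206 ± 355. Cd36 stood at 10106 ± 567 CPM in sham and 4396 ± 231 in TAC, the endothelial surface gene Ly6c1 at 3692 ± 204 and 1485 ± 194, and Btnl9 at 2967 ± 578 and 984 ± 36.2 (SD, n = 2). Col3a1 stood at 66.3 ± 20.8 CPM in sham and 271 ± 53.5 in TAC (SD, n = 2). The endothelial junction genes Pecam1 and Cdh5 had log2 fold changes of -0.27 ± 0.22 and -0.29 ± 0.39 (SE).

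Of 7907 genes tested in endothelial-like cells, 0 passed at an adjusted p of 0.05 in edgeR's quasi-likelihood test, 781 had an unadjusted p under 0.05, and DESeq2's Wald test called 197, of which 111 were higher and 86 lower in TAC. The test had little power here: in simulated data with these libraries' means and spread it called 4 of 100 genes with a 4-fold change and 28 of 100 with a 16-fold change. The summed endothelial-like counts were 1012395 and 1193428 in sham and 1605333 and 611175 in TAC. The class drew on different clusters: one led by Kdr, Btnl9 and Cd36 held 28.1% and 34.6% of sham and 8.9% and 10.7% of TAC endothelial-like cells. One led by Apold1, Sele, Irf1 and Icam1 held 8.9% and 7.5% of sham and 23.7% and 25.3% of TAC cells. A cluster led by Ppp1r15a, Hspb1 and Btg2 held 10.4% and 16.1% of sham and 21.1% and 20.4% of TAC cells. One led by Hspa1a held 14.1% and 17.9% of sham and 19.3% and 17.8% of TAC cells, and one led by Cdh13 held 38.5% and 23.9% and then 27.0% and 25.8%. The division into clusters changed with the settings. Its adjusted Rand index, which is 1 for identical clusters, was 0.18 with 1000 variable genes and 0.418 at resolution 0.4. It was 0.503 with 15 principal components and 0.7 at resolution 1.2. The broad class stayed the same for 94.6% to 98.9% of cells.

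The genes with the smallest p in each direction had adjusted p = 0.159 in edgeR. Higher in TAC were Cenpf at a log2 fold change of 5.07 ± 0.56, the interferon-induced GTPase gene Iigp1 at 2.22 ± 0.29, Hsph1 at 4.41 ± 0.62 and Hspa5 at 1.32 ± 0.19. Also higher were Ier3 at 2.91 ± 0.42, the nucleolar gene Nop58 at 2.30 ± 0.35 and the co-chaperone gene Dnaja1 at 1.94 ± 0.30 (SE). Diap3 had 1 sham and 398 TAC counts, a ratio of 395 with a 95% counting interval of 70.5 to 15646. Lower in TAC were Cd36 at -1.20 ± 0.16, Rgs5 at -2.71 ± 0.39, the cell cycle inhibitor gene Cdkn1c at -2.22 ± 0.32, Btnl9 at -1.59 ± 0.24, Itm2b at -1.36 ± 0.20 and Ly6c1 at -1.31 ± 0.21 (SE). Ctdspl had 477 sham counts and 1 TAC count, a ratio of 480 with an interval of 85.8 to 19016. Eps8l2 had 365 sham counts and 0 TAC counts, 122-fold lower in TAC against a floor of 3 counts over the group, which is no lower bound if counts are reads. These counts sat in few cells: Ctdspl was found in 6 and 11 sham cells and Eps8l2 in 4 and 3. Cenpf lies on GRCm38 chromosome 1 from 189640606 to 189688086, Hsph1 on chromosome 5 from 149614287 to 149636376 and Btnl9 on chromosome 11 from 49165585 to 49187159, all on the minus strand and annotated as protein-coding.

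Of the genes named whatever their result, Col3a1 had a log2 fold change of 2.03 ± 0.55 (SE; edgeR adjusted p = 0.375), Sparc of 0.63 ± 0.20 and Vim of 0.38 ± 0.23. Col4a1 had 0.42 ± 0.20, Fn1 -1.70 ± 1.27 and Acta2 -2.14 ± 0.51 (SE), and none of these passed (edgeR adjusted p of 0.321 or more). Fn1 turned to 0.86 and Cdh5 to 0.21 without Sham replicate 2. Col1a1 had 0 sham and 55 TAC counts, 18.2-fold higher in TAC against a floor of 3 counts over the group, which is no lower bound if counts are reads. These Col1a1 counts sat in few cells, 6 of 507 in TAC replicate 1 and 1 of 225 in TAC replicate 2, against 0 of 415 sham cells. Tagln had too few counts to be tested. Col3a1 passed when each cell was reduced to 200 detected genes (1.93; edgeR adjusted p = 0.00734) and did not in DESeq2 (1.95; adjusted p = 0.113). The count of 0 genes became 420 without Sham replicate 1, 1524 without Sham replicate 2, 18 without TAC replicate 1 and 25 without TAC replicate 2, where the remaining pair alone gave the spread. It became 40 with cells thinned to 500 counts, and 319 and 140 on the number of cells with each gene, before and after reduction to 200 detected genes, the last pair chosen after seeing the data.

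**Figure D2:**
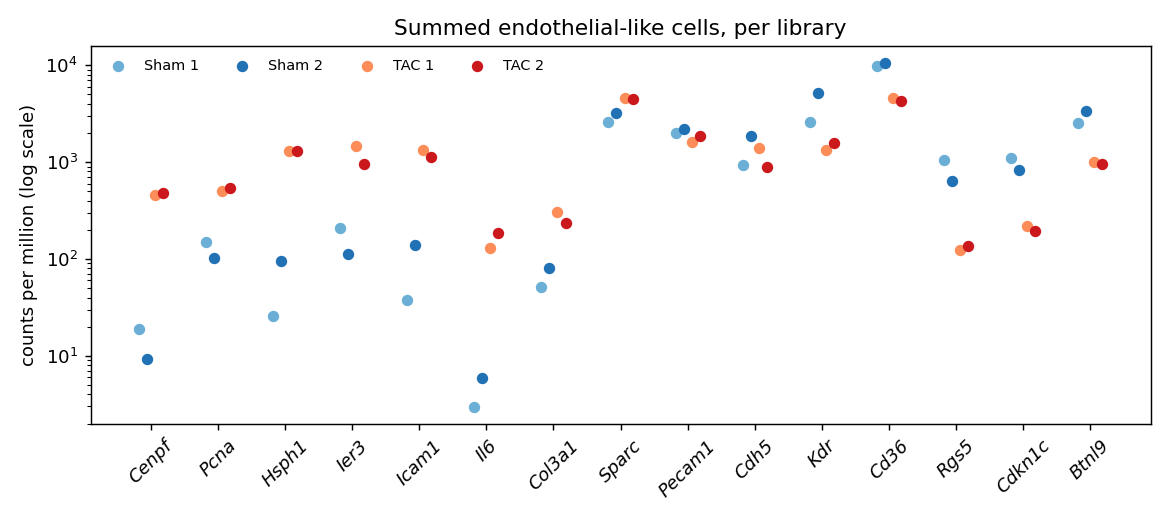
CPM on a log axis of 15 genes in the summed endothelial-like cells, with 1 point for each of the 4 libraries. No gene passed over all genes tested; Cenpf, Hsph1 and Icam1 lay higher in both TAC libraries and Cd36, Rgs5 and Btnl9 lower, while Cdh5 overlapped between the groups.

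Of the 22 gene lists fixed beforehand, 6 moved as sets in endothelial-like cells in camera, and all 6 had adjusted p = 0.602 with an estimated correlation. The cell cycle list was higher in TAC (camera adjusted p = 1.26e-09; adjusted p = 0.602 with an estimated correlation). Of its 35 measured genes 33 lay above 0, with 0 rising over all genes and 3 adjusted over the list alone: Cenpf, the replication clamp gene Pcna at 2.04 ± 0.39 (SE), and Birc5 with 2 sham and 302 TAC counts, a ratio of 150 with an interval of 41.1 to 1244. The proliferation marker gene Mki67 had a log2 fold change of 3.01 ± 0.86 (SE). The inflammation and adhesion list was higher (camera adjusted p = 2.87e-05; adjusted p = 0.602 with an estimated correlation), with 20 of 21 genes above 0, 0 rising over all genes and 11 adjusted over the list alone. Among them were Icam1 at 3.80 ± 0.61, Il6 at 5.09 ± 1.01, Selp at 7.18 ± 1.13 and the chemokine gene Cxcl2 at 6.14 ± 1.25 (SE). Il6 was found in 1 and 1 sham and 22 and 19 TAC cells.

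The capillary list was lower in TAC endothelial-like cells (camera adjusted p = 0.000420; adjusted p = 0.602 with an estimated correlation), with 0 of 15 genes falling over all genes and 10 adjusted over the list alone. Among the 10 were Cd36, the lipase gene Mgll at -1.27 ± 0.22, Kdr at -1.43 ± 0.34 and Rgcc at -1.14 ± 0.27 (SE). The immediate early and dissociation list was higher (camera adjusted p = 0.0315; adjusted p = 0.602 with an estimated correlation), with 24 of 30 genes above 0, 0 rising over all genes and 9 adjusted over the list alone. Among the 9 were Hsph1, Ier3, Dnaja1 and the chaperone gene Hspa8 at 2.21 ± 0.35 (SE). The lymphatic list was higher (camera adjusted p = 0.0418; adjusted p = 0.602 with an estimated correlation), with 0 of 10 genes rising over all genes and 1 adjusted over the list alone, the chemokine gene Ccl21a at 5.67 ± 1.04 (SE), which has near-identical copies and is uncertain. Lyve1 and Fxyd6 had 1.66 ± 0.73 and -1.32 ± 0.84 (SE), and Prox1, the lymphatic identity factor, had 3 sham and 75 TAC counts, a ratio of 24.8 with an interval of 8.2 to 123. The mitochondrially encoded list was lower (camera adjusted p = 0.0418; adjusted p = 0.602 with an estimated correlation), with 0 of 8 genes above 0, 0 falling over all genes and 4 adjusted over the list alone. These were mt-Nd1 at -1.03 ± 0.28, mt-Nd5 at -0.94 ± 0.30, mt-Cytb at -0.78 ± 0.25 and mt-Nd2 at -1.08 ± 0.35 (SE). Mitochondrial ribosomal RNA took 1.54% and 1.40% of these counts in sham and 1.12% and 1.21% in TAC.

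The other lists did not pass in endothelial-like cells. The matrix and collagen list had camera adjusted p = 0.210 with 20 of 33 genes above 0, of which 1 rose and 2 fell adjusted over the list alone and 0 over all genes. The mesenchymal transition list had camera adjusted p = 0.661 with 14 of 22 genes above 0 and 0 called over all genes or adjusted over the list alone, and the TGF-beta target list had camera adjusted p = 0.675. Classes came from clustering on expression, so cells rich in collagen may have been placed in the fibroblast-like class. These lists and the Col3a1 values in endothelial-like cells therefore cannot decide on a transition. Camera gave adjusted p = 0.0754 for the venous, 0.149 for the arterial, 0.174 for the endothelial identity and 0.40 for the endocardial list. The antigen presentation, unfolded protein response and shear stress lists each had camera adjusted p = 0.265, glycolysis and hypoxia 0.323, fatty acid handling and interferon response 0.865, angiogenesis and oxidative phosphorylation 0.870, and ribosomal proteins 1.00. The cell cycle, inflammation and capillary lists passed camera without each library in turn, but the spread in these fits came from 1 pair of libraries, so they do not show stability. The lymphatic call ended without Sham replicate 2 (camera adjusted p = 0.451) and TAC replicate 1 (0.176). The immediate early call ended without Sham replicate 1 (camera adjusted p = 0.0542), Sham replicate 2 (0.0662) and TAC replicate 2 (0.114). The mitochondrial call ended without Sham replicate 1 (camera adjusted p = 0.155), Sham replicate 2 (0.172) and TAC replicate 1 (0.166).

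Marker lists of other cell types also moved in the endothelial-like sums, which does not show that the transcripts came from other cells. The smooth muscle and pericyte marker lists were lower in TAC (camera adjusted p = 0.000650 and 0.000998), each with adjusted p = 0.223 with an estimated correlation. Lymphatic endothelial, macrophage and fibroblast markers were higher (camera adjusted p = 0.00647, 0.0112 and 0.0200), each with adjusted p = 0.223 with an estimated correlation. The endothelial marker list was lower (camera adjusted p = 0.0364; adjusted p = 0.223 with an estimated correlation), and endocardial and heart muscle markers did not pass (camera adjusted p = 0.732 and 0.992). Dendritic cell, neutrophil, T cell, NK cell, B cell, mast cell, erythroid, platelet and epicardial markers, and Schwann markers in endothelial-like cells, had fewer than 5 measured genes and were not tested.

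More TAC than sham endothelial-like cells held at least 1 of 8 mesenchymal transcripts, and most of these cells held Sparc, a matrix-binding protein gene, or Vim, an intermediate filament gene. Sham endothelial-like cells already held Sparc in 40.0% and 43.2% and Vim in 10.4% and 14.3% of cells at 500 counts. Neither gene thus marks a transition by itself, and the combined share does not measure one. With each cell thinned to 500 counts, 50.5% ± 2.30 (SD, n = 2) of sham and 74.5% ± 0.38 (SD, n = 2) of TAC endothelial-like cells held at least 1 count of Col1a1, Col1a2, Col3a1, Fn1, Sparc, Vim, Tagln or Acta2. No cell was shallower than 500 counts, and the median depths were 6618 and 3601.5 counts in sham and 2450 and 2187 in TAC. Median detected genes ran the other way, at 260 and 297 in sham and 340 and 310 in TAC. A detected gene of a kept barcode carried a mean of 25.7 and 13.1 counts in sham and 8.4 and 8.42 in TAC. If counts are reads, 500 counts can stand for fewer molecules in sham, so these shares are not matched for depth. The unthinned shares were 66.7% and 69.6% in sham and 88.9% and 85.8% in TAC. The groups differed by 24.0 percentage points, and the two-sided exact permutation test gave p = 0.333, the smallest it allows. With each cell reduced to 200 detected genes, chosen after seeing the data, the shares were 50.4% and 43.2% in sham and 60.4% and 58.7% in TAC, a difference of 12.7 points.

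At 500 counts per cell, Sparc was found in 40.0% and 43.2% of sham and 64.1% and 60.0% of TAC endothelial-like cells, and Vim in 10.4% and 14.3% and in 21.1% and 24.0%. Col3a1 was found in 0.74% and 1.07% of sham and 7.50% and 6.22% of TAC cells, and Col1a2 in 1.48% and 0.71% and in 4.34% and 2.67%. The smooth muscle actin gene Acta2 was found in 2.22% and 1.07% of sham and 0.79% and 0.89% of TAC cells. With each cell reduced to 200 detected genes, Sparc was found in 40.0% and 33.6% of sham and 45.8% and 44.4% of TAC cells, a difference of 8.32 percentage points against 20.4 at 500 counts. Vim was found there in 11.1% and 15.4% of sham and 14.6% and 16.4% of TAC cells, which overlapped, a difference of 2.29 points against 10.2 at 500 counts (two-sided exact permutation p = 0.667). Acta2 was found there in 0.74% and 0.71% of sham and 0.59% and 0.89% of TAC cells, which overlapped too. Macrophage-like cells, which should lack collagen and Sparc, held any of the 8 transcripts in 52.2% (24 of 46, exact 95% interval 37.0% to 67.1%) and 29.0% (9 of 31, 14.2% to 48.0%) of TAC cells at 500 counts. Their median depths were 3356.5 and 2531 counts. The sham libraries held only 3 and 4 such cells. At 200 detected genes, Sparc was found in 4.35% and 6.45% of TAC macrophage-like cells against 45.8% and 44.4% of TAC endothelial-like cells, and Vim, which macrophages also express, in 26.1% and 22.6% against 14.6% and 16.4%. Col3a1 was found in 4.35% (2 of 46, exact 95% interval 0.53% to 14.8%) and 9.68% (3 of 31, 2.04% to 25.8%) of TAC macrophage-like cells against 6.90% and 9.33% of TAC endothelial-like cells. The intervals overlapped, so a difference from that background was not detectable in these cells.

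**Figure D3:**
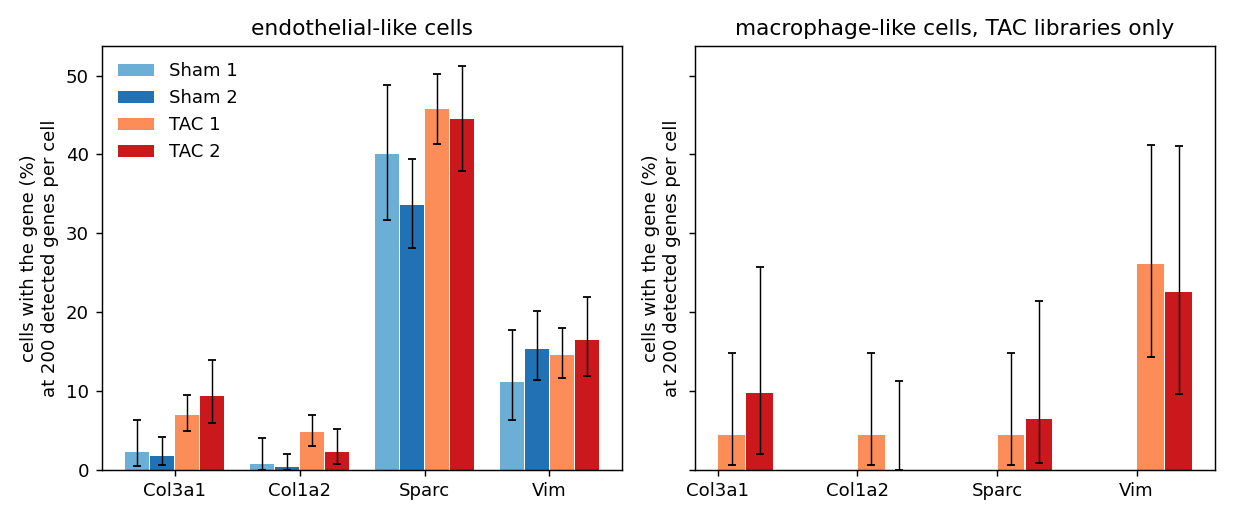
Percent of cells with Col3a1, Col1a2, Sparc or Vim after each cell was reduced to 200 detected genes, in endothelial-like cells of all 4 libraries (left) and in macrophage-like cells of the TAC libraries (right), with exact 95% binomial intervals. Sparc lay at 45.8% and 44.4% in TAC endothelial-like and 4.35% and 6.45% in TAC macrophage-like cells, the Vim shares of the sham and TAC libraries overlapped, and the Col3a1 intervals of the 2 classes overlapped.

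The authors' deposited table listed marker genes of 13 clusters, in 673 entries of which 642 had an adjusted p under 0.05 and all had a positive log fold. In the authors' deposited table cluster 6 had the most entries, 290, led by Col3a1, Col1a2, Mfap5, Dcn, Postn and Mgp, and it held 31 of the 42 matrix and collagen genes and 11 of the 33 mesenchymal transition genes. Col3a1 was given in 98.1% of the cells of cluster 6 and 7.8% of the other cells in the authors' deposited table, and Col1a1 in 55.0% and 0.8%. In the authors' deposited table cluster 0 was led by Gpihbp1, Fabp4, Ly6c1, Cav1, Pecam1 and H2-K1, and held 8 of the 17 endothelial markers and 5 of the 15 capillary genes. Cluster 8 of the authors' deposited table was led by Lyz2, H2-Ab1 and Cd74 and held 12 of the 16 macrophage markers. In the authors' deposited table cluster 9, led by the adhesion genes Sele and Selp, held 7 of the 26 inflammation and adhesion genes and 5 of the 15 venous genes, with Selp in 30.5% of its cells and 0.3% of the others. Further clusters in the authors' deposited table were led by Rgs5, by Scn7a and Plp1, by Il1b, by mitochondrial genes and by the haemoglobin gene Hbb-bs. Which cells the authors' deposited table covers and its log base are not given in the sources used here.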

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

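The values in barcodes under 200 detected genes, and the tests of whether a larger number of detected genes per cell explains a pattern, were chosen only after the results were seen.

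Collagen transcripts also appeared in barcodes that entered no comparison of cell classes. Among barcodes under 200 detected genes, Col3a1 was found in 28.57% of 98 and 20.21% of 475 in TAC replicates 1 and 2, and Col1a2 in 32.65% and 14.74%. In the sham libraries Col3a1 was found in 1.84% of 652 and 2.65% of 490, and Col1a2 in 1.23% and 0.82%, and the highest upper 95% bounds were 4.49% and 2.40%. The median number of detected genes in these barcodes was 64.5 and 88.5 in sham and 163.5 and 101 in TAC.

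Col3a1 was found in more TAC than sham endothelial-like cells. With every cell reduced to 200 detected genes its edgeR adjusted p was 0.00734, within a range of 0.00246 to 1.00 over the alternatives. An equal number of genes per cell thus did not remove the difference. The genes were drawn at random whatever their counts, so cells with more detected genes can still give more weakly expressed genes. Detection depth as the cause therefore stays open. Free RNA from fibroblasts stays open: at 200 detected genes Col3a1 was found in 4.35% and 9.68% of TAC macrophage-like cells against 6.90% and 9.33% of TAC endothelial-like cells, with overlapping intervals. Levels of fibroblast genes in endothelial-like cells of TAC replicates 1 and 2 were 0.931% and 1.01% of the fibroblast-like level for Col3a1, 0.900% and 0.713% for Col1a2, 1.15% and 1.45% for Postn, 1.2% and 1.26% for Mfap5, 0.341% and 0.815% for Dcn, and 12.2% and 3.35% for Fn1. In macrophage-like cells they were 0.512% and 1.04% for Col3a1, 0.82% and 0.0% for Col1a2, 2.64% and 0.923% for Postn, 0.0% and 0.0% for Mfap5, 0.0% and 2.35% for Dcn, and 26.8% and 23.2% for Fn1, from at most 6 cells with a gene, too few to decide whether 1 ratio holds. At 200 detected genes Fn1 was found in 10.9% and 3.23% of TAC macrophage-like cells. It was found in 12.3% and 9.26% of TAC fibroblast-like cells, so its ratios may not gauge free RNA from fibroblasts. A change in endothelial cells after TAC also stays open and was not tested.

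Cell cycle genes were higher in TAC endothelial-like cells. At 200 detected genes per cell camera's adjusted p was 0.000641, which rests on the 6 list genes still measured. TAC cells then held a mean of 1.089 and 1.067 of all 39 list genes, against 0.459 and 0.314 per sham cell. An equal number of genes per cell thus did not remove the difference, but the draw ignored counts, so detection depth stays open. The list had adjusted p = 0.602 with an estimated correlation on summed counts. At 200 detected genes 40 of 507 and 22 of 225 TAC endothelial-like cells held at least 4 of the 39 genes. In 1000 shuffles of each gene over the cells of its library at most 19 and 11 did. In sham 3 of 135 and 1 of 280 cells did, against at most 2 and 1. Free RNA spread evenly over cells would scatter these genes and not give the TAC excess. The shuffles also remove differences between cells in complexity and in the amount of free RNA. Uneven free RNA from other cycling cells therefore stays open. Col3a1 or Col1a2 was found in 3 of 40 (7.5%) and 2 of 22 (9.09%) of the TAC cells with at least 4 of the genes. It was found in 11.1% and 11.3% of the other TAC endothelial-like cells. This cannot decide on doublets with fibroblasts, because cells rich in collagen may have been placed in the fibroblast-like class. At 200 detected genes Col3a1 was found in only 36.2% and 50.0% of TAC fibroblast-like cells themselves. A candidate explanation is that some endothelial cells were cycling 1 week after TAC. It remains a hypothesis. Doublets with cycling cells of other types, fibroblasts among them, uneven free RNA and a difference in library preparation stay open.

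The inflammation and adhesion list and the immediate early and dissociation list were higher in TAC endothelial-like cells. At 200 detected genes per cell camera's adjusted p was 0.00336 for inflammation, on 7 measured genes, and 0.000832 for immediate early genes, on 25. An equal number of genes per cell thus did not remove the difference, but the draw ignored counts, so detection depth stays open. Both lists had adjusted p = 0.602 with an estimated correlation on summed counts. Handling stress of whole libraries cannot be told apart from the operation, because both coincide with the groups. Schwann-like and unnamed cells held a mean of 2.10 and 2.45 of 31 immediate early genes in sham and 5.11 and 5.0 in TAC, a gap of at least 2.55 genes as such stress would give, in 10 to 22 cells per library. Macrophage-like cells went the other way, with 8.33 and 7.50 in sham, in 3 and 4 cells, and 4.00 and 2.97 in TAC. So did fibroblast-like cells, with 5.75 in sham replicate 2, in 4 cells, and 3.99 and 4.02 in TAC. These sham cells are too few to decide on such stress. Of the inflammation list, Schwann-like and unnamed cells held 0.40 and 0.55 genes in sham and 0.84 and 1.13 in TAC. Macrophage-like cells held 3.0 and 1.5 and then 1.33 and 1.06. Fibroblast-like cells held 0.5 in sham replicate 2 and 0.92 and 1.13 in TAC. A response of endothelial cells to TAC stays open and untested.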

How the results depend on the processing

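Tests on numbers of cells with each gene, on cells reduced to 200 detected genes, without shared barcodes, on all deposited barcodes and on the 100 cells with the most detected genes were chosen after the results were seen, as was the block with an estimated correlation. With 1 library left out, 1 library stood against 2, the pair alone gave the spread, and the lone library was assumed to vary like it. Over all cells, the 6 genes became 342 without a filter, 1 without called doublets, 652 on numbers of cells, 171 at 200 detected genes, 92 with all deposited barcodes, 445 in DESeq2, and 51 to 2659 with 1 library left out. All 6 were called in the same direction in these alternatives, except that 5 were called at 200 detected genes, 4 with the stricter cell filter and 1 without called doublets.

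In endothelial-like cells the 0 genes became 146 without a filter, 40 at 500 counts per cell, 319 on numbers of cells, 140 at 200 detected genes, 197 in DESeq2, and 18 to 1524 with 1 library left out, and stayed 0 under the other alternatives without a block. Of the 140 genes, 130 were among the 319 in the same direction and 60 among the 197. The 6 gene lists became 0 with an estimated correlation, where all 6 had camera adjusted p = 0.602, and 3 to 5 with 1 library left out. Fry called 2 lists, the mitochondrial one and oxidative phosphorylation, which is not among the 6. In fry the adjusted p was 0.0726 for cell cycle, 0.132 for capillary, inflammation and immediate early genes and 0.213 for lymphatic genes. Lymphatic genes had camera adjusted p = 0.0617 without a filter, 0.116 without doublets, 0.0956 at resolution 0.4, 0.216 at 500 counts and 0.0191 to 0.451 with 1 library left out, and had too few measured genes on numbers of cells. Mitochondrial genes had 0.0531 without a filter, 0.0589 at resolution 0.4 and 0.0191 to 0.172 with 1 library left out in camera. Immediate early genes had 0.0742 without doublets and 0.0110 to 0.114 with 1 library left out in camera. Over all cells, fry gave adjusted p = 0.054 for matrix, mesenchymal transition, endothelial identity, inflammation and antigen presentation genes, 0.106 for endocardial and 0.183 for arterial genes. There, camera gave unfolded protein response genes 0.0533 without a filter and 0.0769 without doublets, antigen presentation genes 0.198 without doublets, and endocardial and antigen presentation genes 0.0522 with all deposited barcodes, as adjusted p. At 200 detected genes arterial and antigen presentation genes had camera adjusted p = 0.211 and 0.350, and antigen presentation genes had 0.166 on numbers of cells. The cause was not tested for any of these.

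With the replicate number as a block, 290 genes were called over all cells and 142 in endothelial-like cells, and mitochondrial and immediate early genes had camera adjusted p = 0.0936 and 0.0670. Over all cells the block ended the call of the unfolded protein response list (camera adjusted p = 0.106), and it ended no other list call. In endothelial-like cells it added the venous list (camera adjusted p = 0.0414; adjusted p = 0.735 with the block and an estimated correlation). With both, the 6 called lists became 0, each with adjusted p = 0.735, on 1 residual degree of freedom. Nothing says that the numbers pair the samples: deviations of the replicates 1 of both groups correlated across genes at -0.043 over all cells and -0.042 in endothelial-like cells.

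Over all cells the log2 fold change turned sign for Col4a1 (-0.06 on numbers of cells, -0.03 to 0.43 with 1 library left out), Sparc (-0.11 on numbers of cells), Acta2 (0.13 with all deposited barcodes, -0.40 to 0.11 with 1 library left out) and Cd74 (0.59 without doublets, 0.70 on numbers of cells). In endothelial-like cells it turned for Fn1 (-3.02 to 0.86) and Cdh5 (-0.71 to 0.21) with 1 library left out. Each of the leave-one-out turns came without Sham replicate 2, none of these genes had passed, and the cause was not tested. Of the other values for named genes, 433 over all cells and 437 in endothelial-like cells kept direction and side of the threshold, 199 and 235 newly passed it and 8 and 0 lost it. Differences in class shares and in the share of endothelial-like cells with any of the 8 mesenchymal transcripts kept their direction in every alternative that gave a value. For single transcripts the difference turned for Acta2 (-0.81 points to 0.01 at 200 detected genes) and Fn1 (-0.41 to 0.01 unthinned), and the cause was not tested. There were 15 clusters with 1000 variable genes and 5 at resolution 0.4, where no cluster stayed unnamed. An adjusted p under 0.001 with a deposited log fold above 0.5, whose base is unknown, left 392 entries of the authors' deposited table. With 2 libraries per group, the gene test called 28 of 100 simulated genes with a 16-fold change in endothelial-like cells, so smaller changes were mostly below its reach.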

Other observations

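The values below on numbers of cells and on barcodes under 200 detected genes were chosen after the data were seen, and no explanation of them was tested.

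On the number of endothelial-like cells with each gene, over all genes tested in edgeR, 10 of 14 measured cell cycle genes rose, 8 of 14 inflammation and adhesion genes rose and 1 fell, 11 of 28 immediate early genes rose and 1 fell, and 9 of 14 capillary genes fell. Of 18 matrix and collagen genes 5 rose and 2 fell, and of 9 mesenchymal transition genes 2 rose. Of 9 fatty acid and lipid genes 4 fell. With each cell reduced to 200 detected genes, 4 of 6 cell cycle genes rose, and 4 of 7 inflammation and adhesion genes rose and 1 fell. There 10 of 25 immediate early genes rose and 0 fell, and 4 of 13 capillary genes fell. The endothelial identity list, with 4 of 21 genes falling on the unreduced numbers of cells, had camera adjusted p = 0.00429 on them, 0.174 on summed counts and up to 0.773 over the alternatives. The oxidative phosphorylation list was higher in fry, which asks whether its genes move one way on balance (adjusted p = 0.0196), but had adjusted p = 0.870 in camera.

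Among barcodes under 200 detected genes, the haemoglobin gene Hbb-bs took 27756 and 6013 CPM in the sham libraries and 37.7 and 1007 in the TAC libraries. It was found in 3.37% and 2.45% of sham and 2.04% and 1.68% of TAC barcodes, with overlapping 95% intervals. The lysozyme gene Lyz2 took 697.8 and 345.6 CPM in sham and 581.2 and 481.6 in TAC, which overlapped between the groups. The cytokine gene Il1b was found in 0.46% and 1.22% of sham and 3.06% and 4.63% of TAC barcodes. These genes were not tested between the groups.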
